A study of Homo sapiens with 8 samples.

How the data were processed

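CIP-seq was used to map DNA held by TOP2A, the topoisomerase that cuts both strands of a duplex and stays bound to the cut ends until it reseals them. Per the labels' protocols, cells of CCRF-CEM, an established T-lymphoblastic leukaemia line, were treated with etoposide at 25 µM for 1 h, with p-benzoquinone at 8 µM for 4 h, or with the vehicle DMSO at 0.05%. Whether a DMSO library stands for the shorter or the longer vehicle time was not given per sample. Lysates were sonicated to fragments of 250 to 750 bp, TOP2A was captured with an antibody, and calf intestinal phosphatase released the bound DNA. Per the labels' protocols, the libraries were sequenced as single reads of 50 nt. Each treatment had 2 libraries, replicate 1 from pre-amplified DNA and replicate 2 from unamplified DNA, and 2 further libraries were inputs, so that the labels describe 8 libraries. The descriptions of the etoposide and p-benzoquinone libraries of replicate 2 mention amplification while their titles call them unamplified; the titles were followed. Nothing in the labels says whether the libraries of a treatment came from separate cultures.

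The processed data were 3 region files, each pooling the libraries of replicates 1 and 2 of a treatment, per the labels. Values for the input libraries were not used here. Per the submitters' processing notes, Bowtie2 2.1.0, SAMtools 0.1.19 and the hg38 build were used; the region caller, its threshold and the use made of the inputs are not given in the sources used here. The value the authors deposited for each region is a signal, a scaled read number of at least 0 whose scale is not stated. It was not taken as RPM: the values sum to 2306750 for DMSO and 6706920 for etoposide, more than 2 pooled libraries in that unit can reach when each read counts once, while the sum of 1214300 for p-benzoquinone does not settle it. Nor is a depth per library stated, so the number of reads behind each file is unknown. The values were used to describe, rank or filter regions. Where they or a minimum value are set side by side between files, a common scale is assumed that no source states. Each file is a single pooled sample per treatment. The design had no test between treatments. After the data were seen, limma 3.58.1 in R 4.3.3 was run with a trend on log2 shares of midpoints, plus 0.5, of 8030 genes in the 6 libraries told apart below, with the library set as a block and without it, at a Benjamini-Hochberg adjusted p under 0.05. The sets were defined from the data and not assigned to the labelled replicates, so these fits are exploratory. Counts were simulated with 200 genes changed after etoposide, all with at least 50 midpoints over the 6 libraries. Against DMSO, the blocked fit called 28.0% of genes changed 2-fold and 81.5% of those changed 4-fold. It called 5 and 1 of 7830 unchanged genes. Changes at genes with fewer midpoints or in other comparisons were not simulated for this fit. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

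The names column of the files lists the regions joined in each row. Among rows with names of a single region and a value under 5, 99.5% in the DMSO file, 99.99% in the etoposide file and 97.7% in the p-benzoquinone file lay within 0.011 of a whole multiple, from 8 up, of either of 2 constants per file. Rows that joined several regions did so in 18.4%, 13.1% and 21.5% of cases. Unmerged rows under a value of 20 were therefore attributed to a library by the constant they fitted, and rows fitting both, neither or lying above that value were shared out at random in the proportion of attributed rows of similar value. Which constant belongs to the amplified library was not inferred. In each file, the library with the larger share of regions under 100 bp was placed in library set 1 and the other in library set 2. Placing the libraries by their overlap across treatments gave the same sets for 6 of 6 libraries. This split was chosen after the data were seen, and serves as a technical batch.

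Analyses covered chromosomes 1 to 22 and X in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions came from a RefSeq table of 19974 protein-coding genes on the same assembly, which gives neither strand nor exons, and no genome sequence was used here. The planned classes of promoter, UTR, exon and intron were replaced by nearness to either end of a protein-coding gene, by gene body and by intergenic sequence, and the planned upstream flank by 2000 bp on both sides. Assembly gaps were replaced by 100 kb windows with no region in any file, which left 2758.9 Mb. Overlap of at least 1 bp and annotation were set against 100 random placements that kept number, width and chromosome; the smallest two-sided p these can give is 0.0198, and it concerns placement within these files. Per gene, the log2 ratio of region midpoints in the gene and its flanks, plus 0.5, over all midpoints of the file was taken with an exact Clopper-Pearson counting interval at 95%. Genes needed at least 20 midpoints over the files compared, and a 2-fold difference was used for counts of genes. Simulations for the correlation of the drug ratios were run with a single share per gene and with a share per gene and library set. Counts expected from counting error alone came from 100 simulations in which the share of midpoints in a gene did not differ between files. They did not model the library sets. Data were simulated for etoposide and DMSO with 200 genes changed 2-fold, drawn from 3252 genes with at least 50 midpoints over both files. The interval lay on the true side of 0 for 81.5% of changed genes and included 0 for 96.0% of 6696 unchanged genes. The corresponding shares were 79.5% and 97.0% for p-benzoquinone and DMSO and 81.5% and 96.6% for p-benzoquinone and etoposide. Changed genes with 20 midpoints or little more, as many named genes had, were not among those drawn.

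For 20 gene lists fixed before the data were examined, the median density and median log2 ratio were ranked among 10000 random lists matched on gene length in 20 bins. Named genes followed a rule fixed at the same time: per comparison the 10 highest and 10 lowest log2 ratios, per file the 10 genes of at least 10 kb with most midpoints per kb and the 5 regions with the highest value, the list members with most midpoints, and KMT2A, RUNX1, MYC, CDKN2A and CDKN2B. Examples of the list members are printed, and not all are reported here. Alternatives were the 50% of regions with the highest value, a minimum value of 10 or width of 100 bp, merging of regions within 500 bp, overlap of 50% of both regions, equal region numbers, shifts of 50 to 500 kb, gene ends of 2000 bp, covered base pairs, the gene body alone, a minimum of 50 midpoints, other list matching and each library set alone.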

Results

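The series mapped where TOP2A was trapped on DNA in CCRF-CEM T-lymphoblastic leukaemia cells treated with TOP2 poisons. Etoposide, a drug used against leukaemia, blocks the resealing step of TOP2A, and p-benzoquinone is a reactive benzene metabolite that also poisons the enzyme. The DMSO file held 484820 regions, the etoposide file 780256 and the p-benzoquinone file 334474. They covered 90.6 Mb, 151 Mb and 58.9 Mb. Median widths were close, at 161 bp, 161 bp and 158 bp. As each treatment had a single pooled file, the values below have no replicate error, apart from the limma fits named at VAV2.

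Regions were more numerous after etoposide and fewer after p-benzoquinone than in DMSO. On chromosomes 1 to 22 and X, the etoposide file held 1.61 times as many regions as the DMSO file, p-benzoquinone 0.690 times as many as DMSO and 0.429 times as many as etoposide. The authors' median value per region was 5.75 after etoposide, 3.64 in DMSO and 2.95 after p-benzoquinone, and its 95th percentile was 24.9, 11.3 and 7.86. With mean values of 8.60, 4.76 and 3.63, the sums of values over each file followed the same order. Among regions with a value of at least 10, the ratios were 6.05 for etoposide to DMSO, 0.193 for p-benzoquinone to DMSO and 0.0319 for p-benzoquinone to etoposide. The etoposide excess was present in both library sets, at 1.89 times DMSO in set 1 (295189 and 156388 regions) and 1.52 times in set 2 (513800 and 336974). The p-benzoquinone deficit was not. In set 1 the p-benzoquinone library held 1.13 times as many regions as DMSO, and in set 2 it held 0.483 times as many. Among regions attributed to a library, the median value in set 1 was 2.23 in DMSO, 2.99 after etoposide and 2.37 after p-benzoquinone. In set 2 it was 4.23, 6.99 and 3.68. The lower values after p-benzoquinone than in DMSO were thus seen in set 2 alone. The ratios for values of at least 10 were not split by set.

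**Figure D1:**
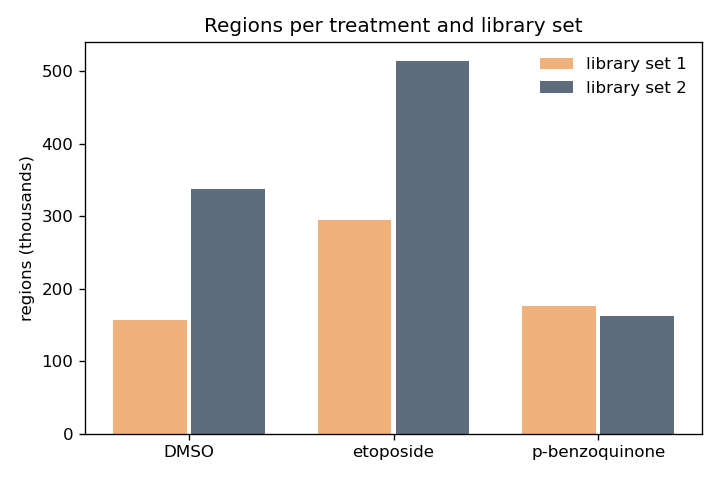
Bars give the estimated number of regions, in units of 1000, for each treatment, in library set 1 and library set 2. Etoposide is highest in both sets, and p-benzoquinone lies above DMSO in set 1 and below it in set 2.

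The libraries of a treatment shared few regions. Rows joined from several regions made up 1.83% of the DMSO file (95% exact interval 1.79% to 1.87%), 3.72% of the etoposide file (3.68% to 3.77%) and 1.31% of the p-benzoquinone file (1.27% to 1.35%). These rows were 5.67%, 9.84% and 2.69% of the smaller library, against 4.53%, 7.49% and 2.31% with the larger library's regions shifted by 50 to 500 kb. Observed overlap was thus 1.25, 1.31 and 1.16 times that of shifted regions. Pairs of libraries from different treatments and the same set overlapped 1.63 to 2.33 times as often as shifted regions, and pairs from different sets 1.19 to 1.35 times. Same-set pairs still shared few regions, 2.57% to 7.54% of the attributed regions of a library.

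**Figure D2:**
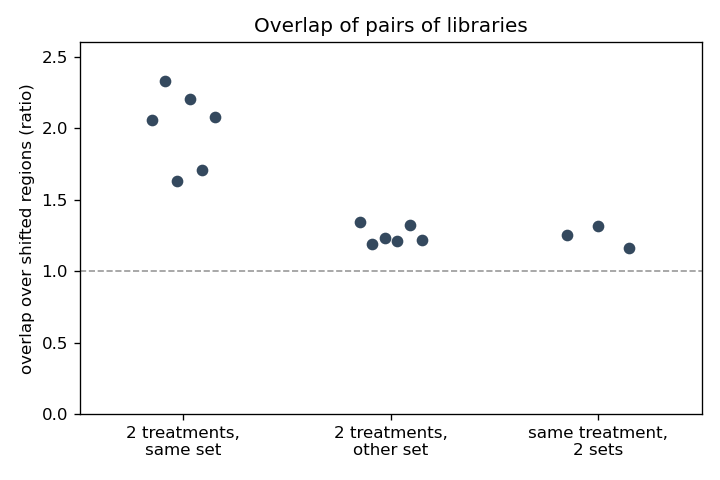
Each point is a pair of libraries, and the vertical axis is the number of overlapping regions over that of shifted regions, with 1 as a dashed line. The 6 same-set pairs from different treatments lie at 1.63 or above, and the 3 pairs from a single treatment at 1.31 or below.

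Regions of different treatments coincided more often than random placements, though most regions were seen in a single file. Of the DMSO regions, 16.5% were overlapped by an etoposide region, against 10.2% for placed regions (range 10.1% to 10.3%), and 7.86% by a p-benzoquinone region, against 4.32%. Of the p-benzoquinone regions, 17.0% were overlapped by an etoposide region, against 9.98%, and 11.4% by a DMSO region, against 6.20%. Each share lay outside all 100 placements (two-sided permutation p = 0.0198, the smallest they can give). The regions found in a single file were 77.3% of DMSO, 83.4% of etoposide and 73.9% of p-benzoquinone, and those overlapped in both other files 1.63%, 1.04% and 2.32%. Among the 1% of regions with the highest value, 71.1%, 79.1% and 66.2% were still found in a single file.

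**Figure D3:**
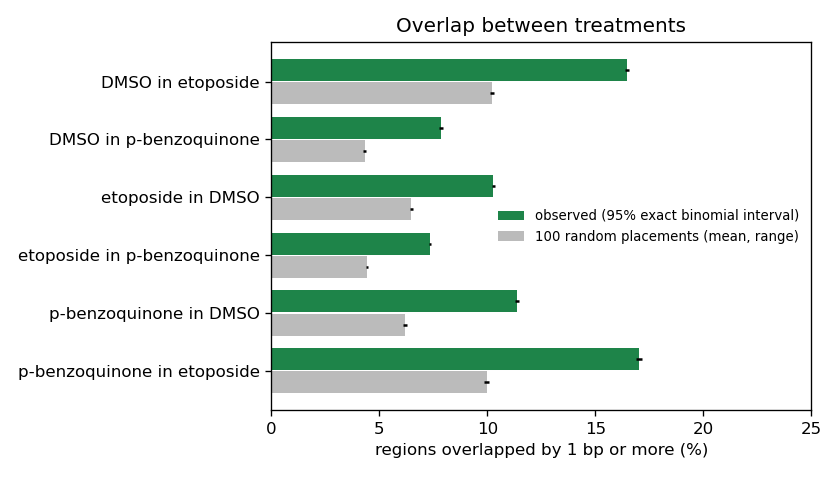
Green bars give the percentage of regions of the file named first that were overlapped in the file named second, with 95% exact binomial intervals, and grey bars the mean and range of 100 random placements. All 6 observed shares exceed their placements, with 17.0% against 9.98% for p-benzoquinone regions in etoposide.

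In all files, regions were sparser at the ends of protein-coding genes and slightly denser within their bodies than random placement gave. Within 1000 bp of a gene end lay 2.11% of DMSO regions, 1.94% of etoposide regions and 1.97% of p-benzoquinone regions, which were 0.867, 0.811 and 0.822 times the placed shares. Protein-coding gene bodies held 45.2%, 44.8% and 45.2%, or 1.05, 1.05 and 1.05 times the placed shares. Bodies of genes neither protein-coding nor lncRNA held 0.591, 0.560 and 0.576 times the placed shares. Each differed from all 100 placements (two-sided permutation p = 0.0198). Around the ends of 10991 genes, the lowest bin of 500 bp had 0.775 of the genome-wide density in DMSO, 0.764 after etoposide and 0.761 after p-benzoquinone. Strand was not used, so the start and the end of a gene were not separated, and neither sequence composition nor input was corrected for.

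**Figure D4:**
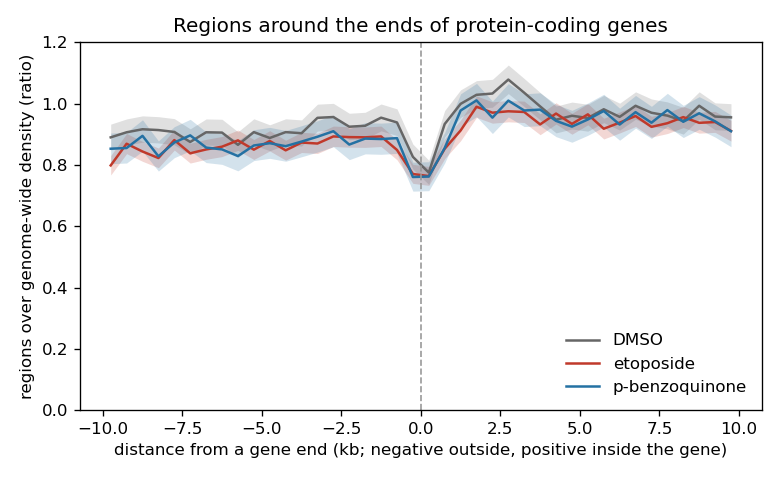
Lines give regions in bins of 500 bp over the genome-wide density, by distance in kb from the ends of 10991 protein-coding genes, with 95% Poisson intervals shaded. The 3 treatments dip together at the gene end, to between 0.761 and 0.775.

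Etoposide was compared with DMSO to ask which genes gained a larger share of TOP2A regions under the drug. Of 6891 genes, 99 had a share at least 2-fold higher after etoposide and 105 at least 2-fold lower. The largest ratios were at GFM1, a mitochondrial translation elongation factor (gene ID 85476; hg38 chromosome 3, 158644527 to 158695581; 22 regions against 2; log2 ratio 2.48, interval 0.75 to 5.91), and RNF212B (26 against 4; 1.87, 0.49 to 3.99). DIO2, a deiodinase that activates thyroid hormone, had a log2 ratio of 1.72, the neurotrophin gene BDNF 1.70, and the B-cell survival factor gene TNFSF13B 1.64. KNL1 and GIN1 stood at 1.57 each, METAP2 and GCH1 at 1.47 each, and SLC22A24 at 1.43 with an interval that included 0. The lowest ratios were at CKLF-CMTM1, a readthrough gene that overlaps its neighbours, with -1.73, at PDCD6IP and STRIP2 with -1.73 each, and at INSYN2A with -1.65. SLC6A6, the taurine transporter, had -1.58, BBS12 and MLPH -1.57 each, SLC22A25 -1.55, and FA2H and FBP1 -1.53 each. Of these 20 genes, 3 (GFM1, BDNF and FBP1) held 0 regions of a treatment in a library set, where no ratio is given. In set 1, GFM1 stood at 1.01 (9 regions against 2). In set 2, BDNF stood at 1.43 (18 against 4) and FBP1 at -2.19 (4 against 13). Of the other genes, 10 moved by more than 1.5 times in a set. Sets 1 and 2 gave 1.01 and 2.28 for RNF212B, 0.96 and 1.71 for KNL1, 0.36 and 2.20 for METAP2, 0.52 and 2.20 for GCH1 and -0.26 and 2.02 for SLC22A24. They gave -2.68 and -1.16 for STRIP2, -0.92 and -1.65 for SLC6A6, -0.92 and -1.77 for MLPH, -0.92 and -1.43 for SLC22A25 and -2.50 and -1.30 for FA2H. Counting error alone gave 118 to 169 genes 2-fold higher and 94 to 138 lower in 100 simulations, so neither count exceeded the simulated range. The 99 higher genes lay below it, and observed log2 ratios spread less than simulated ones (standard deviation 0.432 against 0.453). The same held for p-benzoquinone over DMSO (0.458 against 0.470) and over etoposide (0.460 against 0.489). Simulated ratios thus spread too widely to exclude a small excess of changed genes. A highest ratio as high as that of GFM1 occurred in 46 of these simulations, and a lowest ratio as low as that of CKLF-CMTM1 in 98.

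p-Benzoquinone was compared with DMSO in the same way. Of 5093 genes, 82 had a share at least 2-fold higher and 116 at least 2-fold lower, against 77 to 124 and 96 to 138 from counting error alone. The lowest ratio was at VAV2, which signals from antigen receptors (gene ID 7410; chromosome 9, 133761894 to 133992324; 2 regions against 38; log2 ratio -3.41, interval -6.81 to -1.76). VAV2 held 0.923 of the regions expected at genome-wide density in DMSO, 0.362 after etoposide and 0.0704 after p-benzoquinone. A ratio as low occurred at any gene in 2 of 100 simulations, and a ratio as high as that of PACRGL in 97. These simulations did not model the library sets, whose mix differed between the files. The VAV2 ratio was -2.67 in set 1 (1 region against 8) and -3.29 in set 2 (1 against 30). In limma fits on the 6 libraries told apart, added after the data were seen, VAV2 was the only gene of 8030 with an adjusted p under 0.05 in any comparison, at 0.0182 with the library set as a block and 0.395 without it. UNC5B, a netrin receptor, followed at -3.31, then CUEDC1 at -2.35, SYT2 at -2.01 and CD86, a T-cell costimulatory ligand, at -1.91. BOC stood at -1.79, ZNF469 at -1.69, the Argonaute gene AGO2 at -1.68, and G3BP2 and NPHP4 at -1.65 each. The highest were PACRGL at 1.76, the cytokine receptor gene IL20RA at 1.583, VSNL1 and ODF2L at 1.577 each, and ABCB4, a phospholipid transporter, at 1.56. SLK and HSD17B3 stood at 1.49 each, the transcription factor gene CREB1 at 1.42, and TM9SF2 and ERAP2 at 1.40 each. Of the 20 genes, 3 (UNC5B, BOC and HSD17B3) held 0 regions of a treatment in a library set. In set 1, UNC5B stood at -0.91 (1 region against 2). In set 2, BOC stood at -0.91 (4 against 17) and HSD17B3 at 1.39 (9 against 7). Of the remaining genes, VAV2 and 5 others moved by more than 1.5 times in a set. Sets 1 and 2 gave -1.76 and -2.22 for CUEDC1, -1.02 and -2.41 for SYT2 and -0.91 and -1.35 for NPHP4. They gave 0.62 and 2.82 for PACRGL and 2.89 and 0.31 for SLK, and with the 50% of regions with the highest value SLK stood at 0.17.

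Set directly against etoposide, p-benzoquinone showed 97 genes at least 2-fold higher and 155 lower among 6271, against 88 to 149 and 157 to 221 from counting error alone. The doses and times of the drugs differed. SELENOI, an enzyme of phosphatidylethanolamine synthesis (gene ID 85465; chromosome 2, 26346143 to 26395885), held 0 regions after p-benzoquinone and 21 after etoposide, at least 3.0-fold lower when 3 regions are taken as the limit of a count of 0 and the 21 as exact; with the counting error of both, the interval of the log2 ratio ended at -1.16. A lowest ratio as low occurred at any gene in 37 of 100 simulations, and a highest ratio as high as that of ODF2L in 28. SCGN had a log2 ratio of -2.92, LRIG2 -2.75, RUNX3, a transcription factor of T-cell development, -2.68, and SASS6 -2.62. BAIAP2L1 stood at -2.24, GPR139 at -2.18, ACVR1B at -2.13, TMCO4 at -2.08 and VAV2 at -2.07. The highest ratios were ODF2L at 2.104, UBE2O at 1.93, CEP85 and BBS12 at 1.73 each and SLC4A1AP at 1.50. GLB1L3 and DNTT, the terminal transferase of immature lymphocytes, stood at 1.47 each, SPATA21 at 1.45, VSNL1 at 1.40 and KIAA2012 at 1.38. Of the 20 genes, 8 (the 10 lowest except ACVR1B and VAV2) held 0 p-benzoquinone regions in at least 1 library set, SELENOI in both. In set 2, SCGN stood at -1.80, LRIG2 at -1.61, RUNX3 at -1.97, GPR139 at -0.97 and TMCO4 at -1.37. In set 1, SASS6 stood at -2.42 and BAIAP2L1 at -0.63. Of the other genes, 5 moved by more than 1.5 times in a set. Sets 1 and 2 gave 2.33 and 1.45 for BBS12, 0.75 and 2.11 for SLC4A1AP, 2.12 and 1.32 for SPATA21, 3.07 and 1.19 for VSNL1 and 2.62 and 0.92 for KIAA2012.

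The log2 ratios of the drugs over DMSO correlated across 5080 genes, which are not independent replicates, at r = 0.56. Unchanged groups sharing the DMSO file gave 0.47 to 0.52. The covariance was 0.0974, against 0.0818 to 0.0971 in the simulations. The drugs had 8 genes 2-fold higher in common and 12 lower. Independent lists would share 0.264 and 1.53, and unchanged groups with a shared DMSO file gave means of 12.7 and 13.1. The DMSO file could not be split into parts of 2 libraries each, so part of any excess may come from that file. Set 1 made up 31.7% of the regions in DMSO, 36.5% after etoposide and 52.0% after p-benzoquinone. Simulations unchanged within each set but with this mix, added after the data were seen, gave r of 0.48 to 0.55 and a covariance of 0.0851 to 0.101, a range that holds the observed covariance, while the observed r lay above all 100 of them.

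Across 2782 windows of 1000 kb, the log2 ratio of etoposide over DMSO was lower where protein-coding genes were more numerous (Spearman rho = -0.39 over windows). Within library set 2 rho was -0.408 and within set 1 it was -0.00412. For p-benzoquinone over DMSO, rho was -0.28 with both sets pooled, -0.0359 within set 1 and -0.0435 within set 2, so the pooled relation did not hold within sets.

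Preset gene lists were ranked against length-matched random lists. Of 120 percentiles, 20 lay outside the central 95%, where chance gives 6, and 9 of these did so for summed regions too. The percentiles are not independent, as each list gave several and some lists share genes, so the excess over 6 was not tested. By library set, 3 of the 20 lay outside on the same side in set 1, 9 in set 2 and 2 in both: the density of olfactory receptor genes after etoposide and the ratio of etoposide over DMSO of ZNF genes. Neuronal genes had a high median density in all files, 1.22, 1.18 and 1.22 times the genome-wide density in DMSO, etoposide and p-benzoquinone (percentiles 99.6, 99.2 and 99.1, but 7.17 for etoposide with the 50% of regions with the highest value). Their summed densities ranked at 98.1, 72.9 and 83.8, inside the central range for both drugs, and their medians at 98.95, 94.5 and 97.1 in set 1 and 92.7, 95.5 and 89.5 in set 2. The members with most regions were SYT1 with 155, 218 and 109 regions and RELN with 113, 197 and 80. Olfactory receptor genes, many of them short and with tied values, were denser than genes of like length with both sets pooled (percentiles 98.6, 100 and 100). This held for etoposide in each set, but the percentiles for DMSO and p-benzoquinone were 49.9 and 50.0 with the 50% of regions with the highest value, 50.0 and 50.0 in set 1 and 82.5 and 50.0 in set 2. Among genes of any length, their median density ranked low in every file (percentiles 0.0, 0.195 and 0.0). That median was 0.751 times the genome-wide density in DMSO, 0.718 after etoposide and 0.551 after p-benzoquinone. The members with most regions were picked for their counts, which favours dense members, so they do not describe the list. OR51B5 held 37, 59 and 27 regions (1.24, 1.23 and 1.32 times the genome-wide density). OR9Q1 held 43, 51 and 16 (1.51, 1.12 and 0.816 times). ZNF genes were sparse in DMSO (median 0.744; percentile 0.0, but 47.5 in set 1), with percentiles of 26.8 and 3.24 after the drugs, and their median log2 ratio of etoposide over DMSO was 0.019 (percentile 100), while the summed log2 ratio was 0.04 with an interval of -0.02 to 0.10. The ZNF members with most regions, likewise picked for their counts, were denser than the list median. ZNF385D held 198, 319 and 134 regions (1.17, 1.17 and 1.15 times the genome-wide density) and ZNF804B 113, 202 and 80 (1.10, 1.23 and 1.13 times). Replication-dependent histone genes had a summed log2 ratio of etoposide over DMSO of 0.47 (counting interval -0.09 to 1.04) from 89 and 40 regions, with the median at percentile 99.96, but at 50.0 with the 50% of regions with the highest value and in set 1, and H2BC4 and H2BC12 held 6 and 5 regions after etoposide and 1 each in DMSO.

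T-cell identity genes held 1.27 times the genome-wide density in DMSO when summed (95% Poisson interval 1.14 to 1.40), 1.11 after etoposide (1.02 to 1.21) and 1.24 after p-benzoquinone (1.09 to 1.41), at percentiles 99.9, 94.3 and 99.4. Their median densities ranked lower, at 96.7, 93.8 and 86.2, and differed by set, at 47.8, 22.3 and 86.5 in set 1 and 99.2, 97.51 and 88.6 in set 2. TOX, a regulator of T-cell development, stood at 1.43, 1.34 and 1.584, and the kinase gene FYN at 1.60, 1.37 and 1.18. Genes of leukaemia translocations had a median log2 ratio of etoposide over DMSO of -0.26 (percentile 0.31), with MECOM at 0.02 and ETV6 at -0.35, while their summed log2 ratio was -0.07 with an interval of -0.20 to 0.06, and the median ranked at 30.7 without length matching and at 21.04 in set 1 and 2.54 in set 2. T-ALL oncogenes had a summed log2 ratio of p-benzoquinone over etoposide of 0.25 (0.03 to 0.47; percentile of the median 97.75, but 93.7 without length matching, 65.8 with the 50% of regions with the highest value, 96.1 in set 1 and 86.1 in set 2), with MLLT10 at 0.44 and FBXW7 at 0.01. Genes often deleted in T-ALL had a low median density in DMSO (percentile 0.61, but 12.2 without length matching, 8.25 for summed regions and 11.8 in set 1). Their median log2 ratio of p-benzoquinone over etoposide was high (percentile 99.87, but 93.0 without length matching and 85.8 in set 1). Their summed log2 ratio was 0.03, with an interval of -0.25 to 0.31. The list includes CDKN2A and CDKN2B, which held 0 regions in every file, so the added 0.5 fixed their ratios. Both medians therefore rest partly on these genes, and no ranking without them is given. Topoisomerase and cohesin genes reached percentile 97.8 for density after p-benzoquinone (81.8 with the 50% of regions with the highest value, 97.2 without genes in blocks, 97.0 in set 1 and 91.5 in set 2), with TOP1 at 1.74 and NIPBL at 1.53 times the genome-wide density. Ribosomal protein genes ranked at 98.1 there among genes of like length (91.3 for summed regions, 50.0 in set 1 and 49.8 in set 2), although their median density was 0.748 of the genome-wide level and their summed density 0.785 (0.627 to 0.970), with RPL39L at 2.56, RPL31 at 0.770 and RPS24 at 0.613. For the ratio of etoposide over DMSO, the other lists lay within the central range, with percentiles of 64.2 for myeloid, 97.1 for erythroid and megakaryocytic, 46.7 for B-cell, 10.4 for hepatocyte, 29.6 for immediate early, 8.87 for electrophile response, 95.4 for heat shock, 23.7 for p53 target, 25.8 for glycolysis and housekeeping and 73.5 for very long genes. Hepatocyte genes nevertheless had a summed log2 ratio of -0.52 (-0.90 to -0.14; percentile 0.64).

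KMT2A, the gene most often rearranged in leukaemia after TOP2 poisons, held 26 regions in DMSO, 32 after etoposide and 11 after p-benzoquinone (gene ID 4297; chromosome 11, 118436492 to 118526832), where 16.6, 26.7 and 11.4 were expected at genome-wide density. The ratio to that number was 1.57 in DMSO (95% Poisson interval 1.03 to 2.30), had an interval of 0.821 to 1.69 after etoposide, and was 0.962 after p-benzoquinone (0.480 to 1.72). RUNX1 (chromosome 21, 34787801 to 35049302) held 58, 76 and 25 regions, or 1.24, 1.01 and 0.777 times the expected number. MYC held 4, 3 and 0, with 1.40 expected after p-benzoquinone, so that a lower density was not detectable there. CDKN2A and CDKN2B, cell-cycle inhibitor genes on chromosome 9, held 0 regions in every file. A stretch of 197 kb around them, from 21816055 to 22013326, had no region midpoint in any file, where 114 regions were expected at genome-wide density.

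Among genes of at least 10 kb, GEM was densest in DMSO (3.67 times the genome-wide density, 95% Poisson interval 1.83 to 6.57), FLRT3 after etoposide (3.42, 2.03 to 5.40) and TMEM100 after p-benzoquinone (4.01, 1.73 to 7.91). In DMSO, etoposide and p-benzoquinone, GEM held 11, 4 and 4 regions, FLRT3 8, 18 and 5, and TMEM100 3, 9 and 8. As the highest of many genes, they were picked for high counts, which the intervals do not allow for. No simulated maximum is given for them. The other 9 of each file were SULT1C4, C5orf58, IL1A, C1orf116, CMTM1, RSPH4A, CAV3, OR1A1 and CT55 in DMSO, from 2.95 to 3.41. They were C8orf88, YIPF5, GPR21, PPIL1, RAD21L1, RAB32, HTR2B, TNFSF18 and FMOD after etoposide, from 2.44 to 3.32. After p-benzoquinone they were IL1A, C6orf62, ZNF2, TMEM171, TAF1D, CDKN2C, CRNKL1, VDAC3 and POLE4, from 3.20 to 3.40.

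The region with the highest value lay at the same place in every file, on chromosome 3 from 93470355 to 93470801 in DMSO, in intergenic sequence 402473 bp from PROS1, with authors' values of 8305 in DMSO, 8051 after etoposide and 8657 after p-benzoquinone. On the numbered chromosomes and X, the next in DMSO lay on chromosome 4 from 49709524 to 49710191 (75.7), within the lncRNA gene EPIC1 on chromosome 22 (69.0), on chromosome 22 from 11212962 to 11213605 (62.8) and within an uncharacterised lncRNA gene on chromosome 12 (60.8). After etoposide they lay within MGAT4C on chromosome 12, from 86305867 to 86306585 (203.6), near CSNK1G3 on chromosome 5 (202.6), within ECI2 on chromosome 6 (200.1) and within CNKSR2 on chromosome X (173.2). After p-benzoquinone, 2 neighbouring regions of chromosome 4 had values of 76.0 and 70.9. A region of chromosome 22 from 11213006 to 11213364 (58.4) and a region of chromosome 8 near HGSNAT (47.7) followed. The highest region, on chromosome 3, bordered a stretch from 91535385 to 93470577 with no region midpoint in any file. The chromosome 4 regions lay near another such stretch, from 49711553 to 51107358. No input values were set beside these regions, so their enrichment over input is unknown.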

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

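The tests in this part were chosen after the results were seen, except the test on HLA genes. A signal stood out in sequences that no comparison above used: the highest values outside chromosomes 1 to 22 and X, on the unplaced sequence KI270467v1. They were 1989 in DMSO, 1936 after etoposide and 2090 after p-benzoquinone. The DMSO value lay between those of the drugs, and no input values were analysed beside them. No biological explanation was tested.

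The libraries of a treatment shared few regions. An offset of coordinates between libraries was argued against, since no distance from 300 to 3000 bp held more than 1.13 times the median density of midpoint distances. Among rows with at least 3 times the minimum value, at most 4.66% were joined from several regions. This does not exclude that shared regions were missed near the minimum. A region with a high value in either library may lie under the minimum in the other. Median values of attributed regions were 2.23 to 2.99 in set 1 and 3.68 to 6.99 in set 2. A difference between kinds of library that runs across the treatments remains a candidate explanation for part of the low sharing. Same-set pairs from different treatments overlapped at least 1.63 times as often as shifted regions, more than any pair from a single treatment. Yet their shared regions were also few, at 2.57% to 7.54% of the attributed regions of a library. Such a difference alone therefore does not account for the low sharing. Same-set pairs were taken from attributed rows alone, and pairs from a single treatment from all rows. Pre-amplification is the difference the labels name, but which library set was amplified was not determined.

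The etoposide file held more regions than the DMSO file. Extra regions only near the minimum value were argued against, since with a value of at least 10 the ratio was 6.05. With at least 3 times each file's own minimum value, which needs no common scale, 428153 regions stood against 167572. Deeper etoposide libraries cannot be told apart from a drug effect, because no source states how values were scaled. If the constant per read were inversely proportional to depth, etoposide would have had 0.880 times the depth of DMSO in library set 1, where it had 1.89 times the regions, and 1.08 times the depth in set 2, where it had 1.52 times the regions. An effect of the drug on TOP2A cleavage stays open and untested, with a single pooled file per treatment.

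Beyond CDKN2A, 134 blocks of at least 300 kb held no region in any file. Protein-coding genes lay in 82 of them, 756 genes in all. Blocks at centromeres were not set apart. Blocks without such genes include chromosome 1 from 125166614 to 143195678. Others held gene families, such as PRAMEF genes on chromosome 1 and GOLGA8 genes on chromosome 15. The longest block with many genes was on chromosome 6 from 28509899 to 33482155, with 171 genes. Reads shared with alternate haplotype sequences may account for the chromosome 6 block. The prediction for HLA genes, written before their values were seen, was met with a density of 0 times the average gene in each file (0 regions in 19 genes, upper 95% limits up to 0.134). DNA lost in this cell line is a candidate explanation for the stretch at CDKN2A and CDKN2B, which was at least 207 kb in each file. Neither test covers the remaining blocks, and the inputs, which would show lost DNA directly, were not analysed here.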

How the results depend on the processing

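The library sets, the minimum value of 10, the minimum width of 100 bp, the rows joined from several regions, the lists without blocks, the summed lists, the simulations by library set and the limma fits were chosen after the data were seen. No paired analysis was possible by replicate number because the files pool the replicates and their columns carry none. In its place, limma with the library set as a block called 0 genes for etoposide against DMSO, 1 (VAV2, lower) for p-benzoquinone against DMSO and 0 for p-benzoquinone against etoposide, and without the block it called 0 in each. A count model run before it, and dropped because the files hold no read counts, made the same calls. Lists matched on GC content could not be run without a genome, and taking the upper part of each file by value cannot inform the ratio of region numbers, which it leaves as it is by construction. The annotation shares in the report kept their direction and their side of the threshold under the alternatives run, as did the overlaps of DMSO regions with etoposide and of p-benzoquinone regions with DMSO and with etoposide; the other 3 overlaps were run in a single setting. Among single lists, 37 alternative percentiles left the central range and 44 returned to it without crossing 50.

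The ratio of region numbers of etoposide to DMSO was 1.51 with regions within 500 bp merged, 6.05 for values of at least 10, 1.67 for widths of at least 100 bp, 1.89 in library set 1 and 1.52 in set 2. For p-benzoquinone to DMSO the same alternatives gave 0.707, 0.193, 0.654, 1.13 and 0.483, a reversal in set 1, and for p-benzoquinone to etoposide 0.468, 0.0319, 0.392, 0.596 and 0.317. The cause was not tested.

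With covered base pairs, which vary more than midpoints, 187 genes were 2-fold higher and 243 lower for etoposide against DMSO, 143 and 198 for p-benzoquinone against DMSO, and 165 higher for p-benzoquinone against etoposide. A minimum of 50 midpoints, which leaves fewer genes tested, gave 11 and 10, 3 and 8, and 8 and 7. The 50% of regions with the highest value gave 74 lower for p-benzoquinone against DMSO and 94 lower for p-benzoquinone against etoposide. Library set 1 gave 65 lower for etoposide against DMSO, 34 and 41 for p-benzoquinone against DMSO and 61 and 59 for p-benzoquinone against etoposide, from fewer genes. FBP1 (1.89, from 3 regions against 0, so fixed by the added 0.5) and SLC22A24 (-0.26) changed sign in set 1; the cause was not tested.

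The number of lists outside the central range became 6 for etoposide density, 7 for etoposide over DMSO and 3 for p-benzoquinone over DMSO with no length matching. It became 1 for p-benzoquinone density and 2 for p-benzoquinone over DMSO with the 50% of regions with the highest value, 3 and 2 without genes in blocks, and 1 for p-benzoquinone over etoposide with summed regions. Library set 1 gave 1 for DMSO density, 1 for etoposide density, 0 for p-benzoquinone density, 0 for p-benzoquinone over DMSO and 1 for p-benzoquinone over etoposide, and set 2 gave 2 for p-benzoquinone density and 0 for p-benzoquinone over DMSO. Among percentiles outside the central range, those that crossed 50 without length matching were for olfactory receptors (0.0, 0.195 and 0.0 for density in DMSO, etoposide and p-benzoquinone), ribosomal proteins (25.6 for p-benzoquinone) and histones (32.4 for etoposide density and 99.3 for p-benzoquinone over etoposide). With the 50% of regions with the highest value they crossed for neuronal genes (7.17, etoposide), olfactory receptors (49.9, DMSO; 50.0, p-benzoquinone), ribosomal proteins (49.97) and histones (50.0 for etoposide over DMSO and 50.005 for p-benzoquinone over etoposide). In library set 1 they crossed for T-ALL oncogenes (8.83 for p-benzoquinone density), olfactory receptors (50.0 for DMSO and p-benzoquinone density), ribosomal proteins (50.0 for p-benzoquinone density) and histones (50.0 for etoposide density and for etoposide over DMSO), and in set 2 for olfactory receptors (50.0) and ribosomal proteins (49.82) in p-benzoquinone density. Tied values of short genes place several of these at 50; the cause of the others was not tested. Depth per library is unknown and limits every ratio.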

Other observations

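The test of the hypothesis in this part was chosen after the results were seen. The densest and the sparsest chromosome by regions per Mb were the same in all files, though the order of others differed. Chromosome 20 was densest, with 216, 324 and 149.9 regions per Mb in DMSO, etoposide and p-benzoquinone, and chromosome 19, which is rich in genes, was sparsest, with 112, 163 and 66.2. Among very long genes, MACROD2 held 575, 949 and 479 regions, or 1.59, 1.63 and 1.92 times the genome-wide density, while CNTNAP2 held 397, 658 and 275, close to the genome-wide level at 0.979, 1.01 and 0.983. No gene density in this report was scaled to that of its chromosome. FLRT3, the densest gene after etoposide, lies on chromosome 20.

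The hypothesis that the drugs shift TOP2A regions towards the same places in both library sets was tested across windows. If it held, log2 ratios over DMSO in windows of 1000 kb would correlate between the sets. Pearson r was -0.0259 for etoposide and -0.0133 for p-benzoquinone over 2782 windows, where the pooled ratios held in both sets would have given about 0.41 and 0.36, values that count the noise of the pooled ratios as signal. At this scale no drug difference held by both sets was seen. Between the sets, r of gene log2 ratios was -0.00257 for etoposide over DMSO (3252 genes) and 0.00502 for p-benzoquinone over DMSO (2035 genes). For p-benzoquinone over etoposide it was -0.046 (2877 genes). Named genes were picked on ratios pooled over both sets, which favours like signs in each, so those signs do not show replication. The r that a true shared difference would give is unknown, because counting noise was not taken out of the ratios. A low r therefore does not decide against such a difference, and rows shared out at random between libraries may also lower r.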
